A study of Caenorhabditis elegans with 2 samples.

How the data were processed

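Chromatin immunoprecipitation and sequencing was performed on whole L3 larvae, and each of the 2 samples was a biological replicate with its own number, per the labels. One label names aly-2 as the antibody target and another describes the experiment as directed at the eGFP-tagged protein; the antibody itself is not given in the sources used here. Library fragments were between 150 and 350 bp, per the labels. The group contained both replicates, and no control samples were analysed here.

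The deposited files were lists of regions on ce11 and ce10. For each replicate and for the pooled replicates the authors deposited a relaxed list of peaks and background regions, made as input for a test of irreproducible discovery rate (IDR). They also deposited an optimal list, the pooled regions kept at the IDR threshold. Per the records that accompany the files, the pooled lists were made from the alignments of both replicates and 1 further file whose role is not stated. The aligner, the peak caller, their versions, and any filter or subtraction of a control are not given in the sources used here.

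Each region's height is the signal value the authors deposited, and how it was scaled is not given in the sources used here. It was used to rank, describe and filter regions within a list, in the correlation between replicates, and, as an analysis added after the data were seen, to compare peaks on X with those on autosomes within each list. The deposited −log10 of the q-value was at its highest value in all 368 optimal peaks, and in 470 pooled regions in total, so it was not used for ranking. The ce11 lists held 17335 pooled regions and 30000 and 26751 regions in replicates 1 and 2, and the ce10 list of replicate 1 also held 30000. The median widths were 396 bp in the pooled and 376 and 420 bp in the replicate lists. The number of listed regions does not measure depth. No read counts were used here, so depth is unknown, and the intervals given for shares of peaks are 95% Wilson intervals over peaks that cover neither depth nor differences between animals.

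Gene positions came from Ensembl release 115 and sequence from the RefSeq copy of WBcel235, and all ce11 regions lay within its chromosome lengths. Lists on ce10 were compared only with each other and by chromosome, against ce11 chromosome lengths, and coordinates were never converted. Each summit was given 1 class from protein-coding genes, in the order within 500 bp of a 5′ end, within 500 bp of a 3′ end, exon, intron and intergenic. The background was the 16851 pooled regions that overlap no optimal peak. These regions came from the same reads and could have passed the authors' threshold, but they can include weak binding sites.

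An optimal peak was found in a replicate when a region of that replicate's list overlapped its summit, and the highest such region gave its replicate height. The number of highest regions taken per replicate equalled the number of optimal peaks, 368. Correlations used 100000 permutations, two-sided, for which the smallest possible p is 1e-05. Chromosome counts were tested with exact binomial tests. Classes, orientations, gene lists and words were tested with Fisher's exact test. All tests were two-sided, and Benjamini-Hochberg adjustment was applied within each family; an adjusted exact p is the adjusted value of an exact test. Odds ratios are conditional maximum likelihood estimates with exact 95% intervals. Calls were made at an adjusted p under 0.05, and for words also at a ratio of shares of at least 1.5.

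The 29 gene lists were fixed before the data were examined, as were the classes, tests, alternatives and the rule for named genes. Of the lists, 21 hold protein-coding genes, tested by members with an optimal summit within 500 bp of the 5′ end against all other protein-coding genes. The other 8 hold noncoding genes, tested by the share of summits within 500 bp of a member against background regions. Most lists were defined by gene name, and the microRNA list found 8 genes where the annotation has 261 of the miRNA biotype. Genes named in the text were those with the 5′ end nearest to the summits of the 20 highest peaks, up to 4 members of each list with the highest peaks, and aly-1, aly-2, aly-3 and unc-119. Named words were the 5 called words with the highest ratio, and GCGCGC was added for its tie. Genes whose bodies hold a summit on X, Y41G9A.17, mom-1 and pks-1, were named after their values were seen. The same holds for wwp-1, and for eef-2 and vha-13 as the genes with the 3′ end nearest to a summit.

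Alternatives changed the build, the overlap rule, the window, the background, the gene assignment or the peak set. Leaving out a replicate meant replacing the optimal peaks by the 368 highest regions of the other replicate. For classes, orientations and noncoding lists the background was then the pooled regions that overlap none of these. It therefore still came from both replicates and could include optimal peaks. After the data were seen, analyses without X, the miRNA biotype in place of the name pattern, and correlations over all pooled regions, over the peaks of lower rank and without the 20 highest peaks were added. So were tests of heights and positions on X, of repeated sequence, of named words between X and autosomes, and of a sequence motif. One pattern weighed among the observations was reworded after its tests had run. Its first tests of the motif, by the share of summits with the core, and of gene density, by the intergenic share alone, were replaced after their results were seen: the outer bases of the motif had not been examined before, while the values behind the new test of gene density had. A summit was counted as repeated when any of 5 words of 36 bases within about 100 bp of it occurred more than once in the nuclear genome; the read length is not given in the sources used here.

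The tests were tested on simulated data with known answers. Of 10 simulated lists of 80 genes with 8 planted peaks each, 10 were called, and of 10 lists without planted peaks 0 were called. In 20 random sets of 368 peaks 0 had a class called. A word planted in 41 of 368 windows was called, and 0 words were called without planting. Peaks that were not planted were placed at random positions. The simulations thus did not cover summits that differ from their flanks in base composition or that gather at gene ends. Analyses were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.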

Results

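Binding of the tagged protein ALY-2 to chromatin was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole larvae of the nematode Caenorhabditis elegans. ALY-2 belongs to the Aly/REF family of mRNA export adaptors. The worms were third-stage (L3) larvae of both sexes of the strain OP217, which carries an integrated eGFP-tagged aly-2 transgene in an unc-119 mutant background. All samples formed 1 group of 2 biological replicates, so the comparisons are between genomic regions and between the replicates, not between conditions. The relaxed list of replicate 1 held 30000 regions, the same number on ce10 and ce11, which may be a cap set in peak calling, and that of replicate 2 held 26751 regions; the read depth behind them is unknown. All coordinates are 1-based on ce11, the same assembly as WBcel235.

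The loci of the tagged gene and of the rescue marker were examined first. No peak of the optimal list lay within 500 bp of aly-2 (chromosome IV, 9147468 to 9148579) or of unc-119 (chromosome III, 10902641 to 10908935). The highest pooled region at aly-2 had a height of 39.6 and rank 539 of 17335, and lay over the 3′ end of the gene at 9148532 to 9148927. It ranked 916 in replicate 1 and 681 in replicate 2. The other family members, aly-1 and aly-3, also lacked an optimal peak, and their highest pooled regions ranked 16854 and 5620. At unc-119 the highest pooled region ranked 14308.

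How many peaks were listed, and how well the replicates ranked them, was asked next. The optimal list held 368 peaks, which were the 368 highest regions of the pooled list, with heights from 43.6 to 178.6 and a median of 53.1. Some overlapped each other, such as those at 835662 to 836057 and 835869 to 836264 on chromosome III, so 368 does not count separate sites. The tests over summits below treated overlapping peaks as independent, so their intervals and p-values can be too narrow. The highest peak lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III, 3867458 to 3867656). It ranked 1 in both replicates, with heights of 86.4 and 98.3. The peak upstream of cdc-48.1, which encodes a p97-type AAA ATPase, had a height of 156.9 and ranked 5 in both replicates (chromosome II, 10563493 to 10563660). All 20 highest peaks were among the 368 highest regions of both replicates (100%, 95% Wilson interval 83.9 to 100%).

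Among all 368 optimal peaks, 140 (38%, 33.2 to 43.1%) were among the 368 highest regions of both replicates. The share was 126 of 184 peaks (68.5%) of higher rank and 14 of 184 (7.61%) of lower rank. Across the 362 peaks found in both replicates, heights had a Spearman rho of 0.18 (permutation p = 0.00049, adjusted p = 0.000686 over 14 correlations) and a Pearson r of 0.52 (adjusted p = 1.75e-05). These values depended on the highest peaks: without the 20 highest, 342 peaks had a rho of 0.034 (adjusted permutation p = 0.529) and an r of 0.13 (adjusted permutation p = 0.0174). Among the 179 peaks of lower rank found in both replicates rho was -0.58 (adjusted permutation p = 1.75e-05). Over the 7025 pooled regions found in both replicates rho was 0.27 and r was 0.58 (adjusted permutation p = 1.75e-05 each). These 3 sets were added after the data were seen. Peaks are not independent replicates, and some overlapping peaks share a replicate region and its height. The optimal peaks were chosen by a pooled height made from the same replicates, which lowers the correlation among them, so their rho does not measure how far the replicates agree. The same choice shapes the shares by rank, including that of the 20 highest peaks. Taken without the pooled list, 143 of the 368 highest regions of replicate 1 (38.9%) were among the 368 highest of replicate 2.

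**Figure D1:**
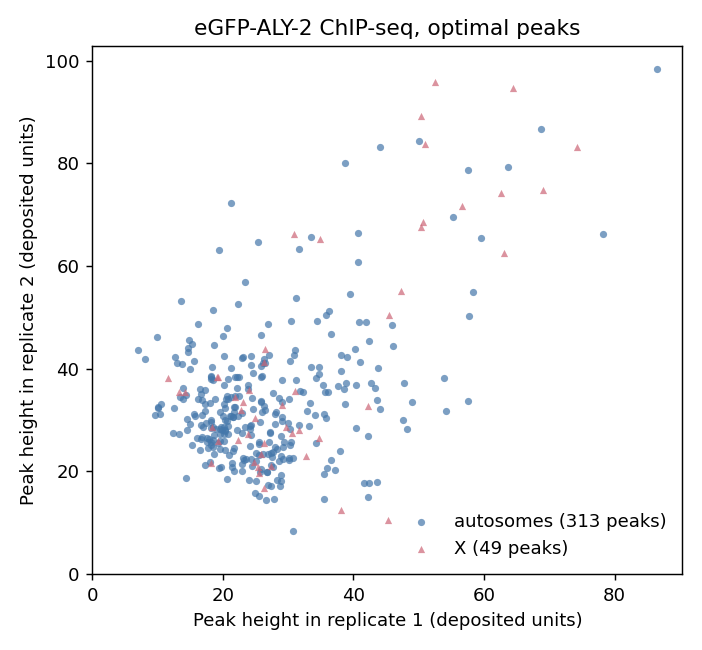
Height of each optimal peak in replicate 1 (horizontal axis) and replicate 2 (vertical axis), in the deposited units, for the 362 peaks found in both; circles are peaks on autosomes and triangles peaks on X. The peak at rpl-3 is the highest in both replicates (86.4 and 98.3); the set was chosen by pooled height, which shapes the cloud of lower peaks.

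The 20 highest peaks were then placed by gene. Besides those at rpl-3 and cdc-48.1, the autosomal peaks lay upstream of or within rpl-35 (height 117.3), the divergent pair rpl-20 and Y17G9B.5 (128.0), the cytochrome c oxidase gene cox-5A (125.8) and Y49A3A.3 (124.3), all within 500 bp of the 5′ end. The peak with rank 20, of height 116.4, had its nearest 5′ end at the pyruvate kinase gene pyk-1, 1415 bp away. Its summit lay 65 bp beyond the annotated 3′ end of eef-2. The peaks of height 139.5 (chromosome I, 4172327 to 4172517) and 126.2 (chromosome II, 5844770 to 5845165) lay beside sls-2.4 and over sls-2.1, which encode SL2 spliced leader RNAs, and the first of them also beside the noncoding gene R12E2.18. A further peak of height 144.1 covered the 5′ end of the noncoding gene Y65B4BR.10.

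The other 10 of the 20 highest peaks lay on chromosome X, and none of these 10 was at a protein-coding 5′ end. Of the 10, 5 were intergenic, among them those at 11094153 to 11094279 (height 158.3) and 9465791 to 9465924 (151.0), whose nearest 5′ ends were a tRNA gene and the noncoding gene ZK899.10. Others lay inside introns of Y41G9A.17 (2996914 to 2997309, 159.6) and of mom-1, which encodes a Porcupine-type acyltransferase (6296383 to 6296778, 144.2). The peak at 5429345 to 5429740 lay in an exon of the polyketide synthase gene pks-1 (136.3). The gene with the nearest 5′ end was 734 bp away for the closest, nspc-17, and 10016 bp away for the farthest, C41A3.6. The remaining nearest genes on X were 21ur-12946, cest-16, F19H6.5, K02D3.5, F20B6.9 and gtr-1.

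Whether peaks followed chromosome length was tested on all 368 peaks. Chromosomes I and III held more peaks than their share of nuclear bases, with 77 peaks (20.9%, 95% Wilson interval 17.1 to 25.4%, 1.39 times the expected number, adjusted exact p = 0.00804) and 69 peaks (18.8%, 1.36 times, adjusted exact p = 0.0157). Chromosome V held fewer, with 50 peaks (13.6%, 0.651 times, adjusted exact p = 0.0024). Chromosome X also held 50 peaks (0.769 times), which did not pass (adjusted exact p = 0.0603), nor did chromosomes II (57 peaks) and IV (65 peaks); these were two-sided exact binomial tests with Benjamini-Hochberg adjustment. The median height was highest on X at 58.3 and lowest on chromosome I at 50.3. Against the chromosome shares of background regions no chromosome passed, with ratios of 1.24 for I, 1.18 for III and 0.763 for V. With the highest regions of replicate 1 alone, without replicate 2, I (1.14) and V (0.781) did not pass, and among the 184 highest peaks I did not (1.01).

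**Figure D2:**
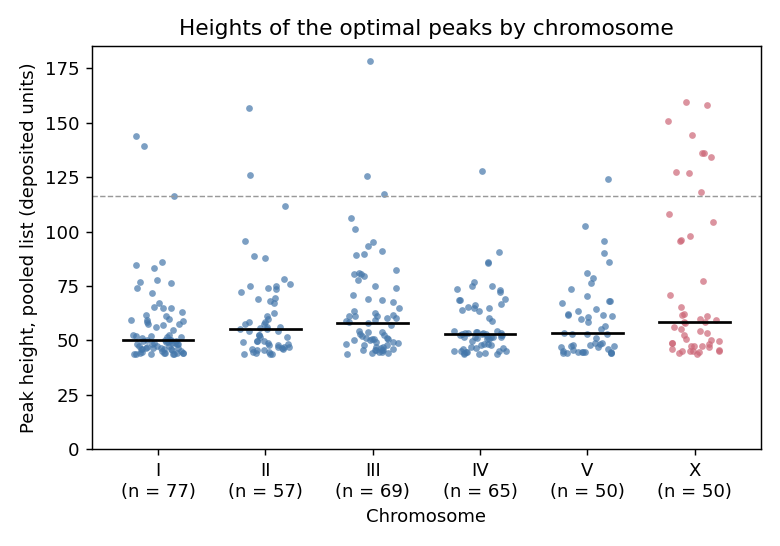
Height of each of the 368 optimal peaks in the pooled list (vertical axis, deposited units) by chromosome (horizontal axis); black lines are medians and the dashed line marks the height of the peak with rank 20 (116.4). Chromosome X holds 10 of the 20 peaks at or above that line.

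The position of summits relative to protein-coding genes was compared with 16851 background regions, the pooled regions that overlap no optimal peak. Summits gathered at both ends of genes. Within 500 bp of a 5′ end lay 145 of 368 summits (39.4%, 95% Wilson interval 34.5 to 44.5%) against 21.8% of background summits (odds ratio 2.33, adjusted exact p = 1.81e-13). Within 500 bp of a 3′ end, and of no 5′ end, lay 116 summits (31.5%) against 18% (odds ratio 2.10, adjusted exact p = 8.96e-10). Introns held 32 summits (8.70%) against 29.3% (odds ratio 0.23, adjusted exact p = 7.82e-21), exons 26 (7.07%) against 11.1% (0.608, adjusted exact p = 0.0143), and intergenic sequence 49 (13.3%) against 19.8% (0.623, adjusted exact p = 0.0022).

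Of the 145 summits at 5′ ends, 102 (70.3%, 62.5 to 77.2%) lay upstream of the nearest annotated 5′ end, with a median offset of -137 bp. Of the 116 at 3′ ends, 89 (76.7%, 68.3 to 83.5%) lay beyond the nearest annotated end, with a median offset of 150 bp. The lower share in exons did not pass with either replicate alone (odds ratio 0.983 without replicate 1 and 0.935 without replicate 2), and the odds ratio for introns was 0.39 without replicate 2. The lower intergenic share did not pass with a window of 250 bp (0.949) or among the 184 highest peaks (0.667).

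**Figure D3:**
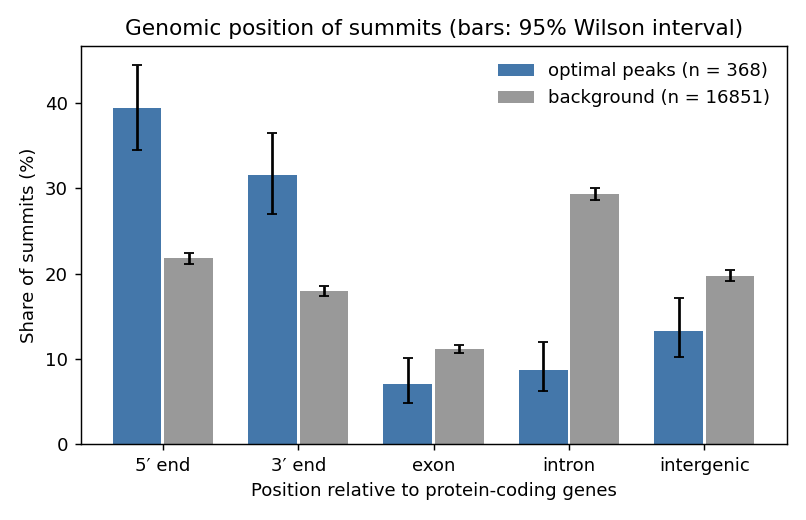
Share of summits (vertical axis, percent) by position relative to protein-coding genes (horizontal axis) for the 368 optimal peaks and the 16851 background regions, with 95% Wilson intervals. Optimal peaks exceed the background at 5′ ends (39.4 against 21.8%) and 3′ ends (31.5 against 18%) and fall below it in introns (8.70 against 29.3%).

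Among the 49 intergenic summits, none of the orientations of the neighbouring protein-coding genes passed Fisher's exact test (two-sided). Between convergent genes lay 6 summits (12.2%) against 5.67% of background summits (odds ratio 2.32, adjusted exact p = 0.181), between divergent genes 18 (36.7%) against 39.8% (0.878, adjusted exact p = 0.769) and between tandem genes 25 (51%) against 54.5% (0.869, adjusted exact p = 0.769). Among the 184 highest peaks, with 26 intergenic summits, the convergent (odds ratio 3.96) and divergent (0.275) classes passed with an adjusted exact p = 0.0223 each, and adjusted p ranged from 0.0223 to 1 over the alternatives.

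Which groups of genes carried peaks was tested with 29 lists. In all, 178 protein-coding genes had a summit within 500 bp of the 5′ end, from 144 distinct peaks, since neighbouring genes can share a peak. Genes for cytosolic ribosomal proteins and for translation factors had such a summit more often than other genes. Of 78 genes for cytosolic ribosomal proteins 12 had such a summit (15.4%, against 0.834% of other genes, odds ratio 21.6, 95% interval 10.4 to 41.3, adjusted exact p = 6.53e-11). The highest were rpl-3 (178.6), rpl-20 (128.0), rpl-35 (117.3) and rps-1 (101.2, chromosome III, 4475441 to 4475836). Of 40 genes for translation initiation and elongation factors 6 had one (15%, odds ratio 20.3, 6.86 to 49.7, adjusted exact p = 9.96e-06). They included eef-2 (65.2), which encodes elongation factor 2, eef-1A.1 (58.8), the initiation factor 3 subunit gene eif-3.C (56.9) and iff-2 (55.1), which encodes an eIF5A protein.

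The translation factors did not pass without replicate 2 (odds ratio 3.85, adjusted exact p = 0.546), and their adjusted p stayed under 0.05 in the other alternatives. For ribosomal proteins the odds ratio was 10.3 with a window of 250 bp and 6.28 against genes with a pooled region at their 5′ end. When each summit counted only for its nearest gene, 8 ribosomal protein genes (odds ratio 16.6) and 5 translation factor genes (20.3) had a peak.

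Of the 8 noncoding lists, those of snoRNA, snRNA and spliced leader RNA genes had more summits near them than the background. Within 500 bp of a snoRNA gene, which encodes a guide for RNA modification, lay 27 of 368 summits (7.34% against 0.944%, odds ratio 8.31, 5.24 to 12.8, adjusted exact p = 9.86e-14). Of these 27 summits, 8 lay in introns, 6 at 3′ ends, 5 at 5′ ends and 3 in exons of protein-coding genes, and 5 were intergenic. The median offset from the snoRNA 5′ end was 29 bp. The highest were at C06A1.9 (156.9, 497 bp from its 5′ end and shared with cdc-48.1), C16D9.11 (95.5), ZK994.7 (90.0) and K11C4.6 (80.8). Near snRNA genes lay 10 summits (2.72% against 0.273%, odds ratio 10.2, 4.55 to 20.7, adjusted exact p = 2.53e-06), among them those at sup-6 (111.7) and R07E5.16 (89.1).

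The spliced leader RNA genes, whose transcripts are joined to pre-mRNAs by trans-splicing, had 5 summits (1.36% against 0.0831%, odds ratio 16.6, 4.64 to 49.0, adjusted exact p = 0.000229). These 5 are also among the 10 at snRNA genes, since the annotation gives all 30 spliced leader genes the snRNA biotype. They included sls-2.4, sls-2.1 and a summit shared by sls-2.2 and sls-2.3 (88.8). Without replicate 2 the odds ratio for snoRNA genes was 5.31, and with a window of 1000 bp it was 5.51. Among the 184 highest peaks it was 16.6 for snRNA genes and 26.7 for spliced leader genes.

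Chemoreceptor genes, a family expressed mainly in sensory neurons, had fewer peaks. Of 1293 members 2 had a summit at the 5′ end, sri-5 (55.9) and srh-16 (44.1) (0.155% against 0.942%, odds ratio 0.163, 0.0196 to 0.598, adjusted exact p = 0.00449). Near genes of piRNAs, the 21U small RNAs of the germline, lay 6 summits (1.63% against 5.06%, odds ratio 0.311, 0.113 to 0.686, adjusted exact p = 0.00449), the highest at 21ur-13952 (91.3) and 21ur-13751 (74.2). Neither passed without replicate 2 (odds ratios 0.219 and 0.695). Chemoreceptors also did not pass among the 184 highest peaks (0.156) or against genes with a pooled region (0.325), nor piRNA genes with a window of 1000 bp (0.501).

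The remaining lists did not pass, and for protein-coding lists a peak here again means a summit within 500 bp of the 5′ end. The respiratory chain and ATP synthase list had 2 of 44 genes with a peak (odds ratio 5.34, adjusted exact p = 0.189), cox-5A (125.8) and the cytochrome c gene cyc-2.1 (63.9). Chaperones had 2 of 59 (3.93, adjusted exact p = 0.282), the chaperonin subunit genes cct-1 (95.8) and cct-8 (72.0), and passed only with a window of 1000 bp (6.2). Both summits lay nearer to the 5′ end of another gene, and no chaperone gene had a peak when only the nearest gene counted. One gene each had a peak among mitochondrial ribosomal proteins (mrps-7, 45.1, odds ratio 1.62, adjusted exact p = 0.825), splicing factors (hrpu-1, 53.1), histones (his-37, 61.2), germline genes (him-17, 64.3) and homeobox genes (ceh-38, 52.2). The mitochondrial ribosomal proteins had no such gene without replicate 1, nor without replicate 2. Near tRNA genes lay 9 summits (odds ratio 1.77, adjusted exact p = 0.293) and near long noncoding RNA genes 5 (2.68, adjusted exact p = 0.165), with the highest at K07C10.8 (72.1) and linc-128 (63.3). For the latter list the odds ratio was 1.53 without replicate 1 and 1.03 without replicate 2.

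No member had a summit within 500 bp of its 5′ end among 16 genes of mRNA export and the THO/TREX complexes, the pathway of ALY-2 (odds ratio 0, 95% interval 0 to 29.1, adjusted exact p = 1). The same count of 0 was found for 26 nuclear pore, 33 proteasome and 21 vacuolar ATPase genes, and for marker lists of epidermis (20 genes), muscle (30), intestine (35) and neurons (35). It was also found for 174 cuticle collagens, 140 neuropeptides and 269 nuclear hormone receptors, and no summit lay within 500 bp of the 20 rRNA or 8 microRNA genes. Peaks at 3′ ends do not enter these counts of protein-coding genes. The summit within Y49A3A.3, for example, lay 189 bp beyond the 3′ end of the vacuolar ATPase gene vha-13. The 95% intervals of the odds ratios of these lists all reached above 1. Some of the zeros did not hold when a replicate was left out, though none of these lists passed. Without replicate 2 a proteasome, a collagen and a neuropeptide gene had a summit, and without replicate 1 a vacuolar ATPase gene did (odds ratio 6.6). Near microRNA genes lay 1 summit without either replicate (22.9 each).

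**Figure D4:**
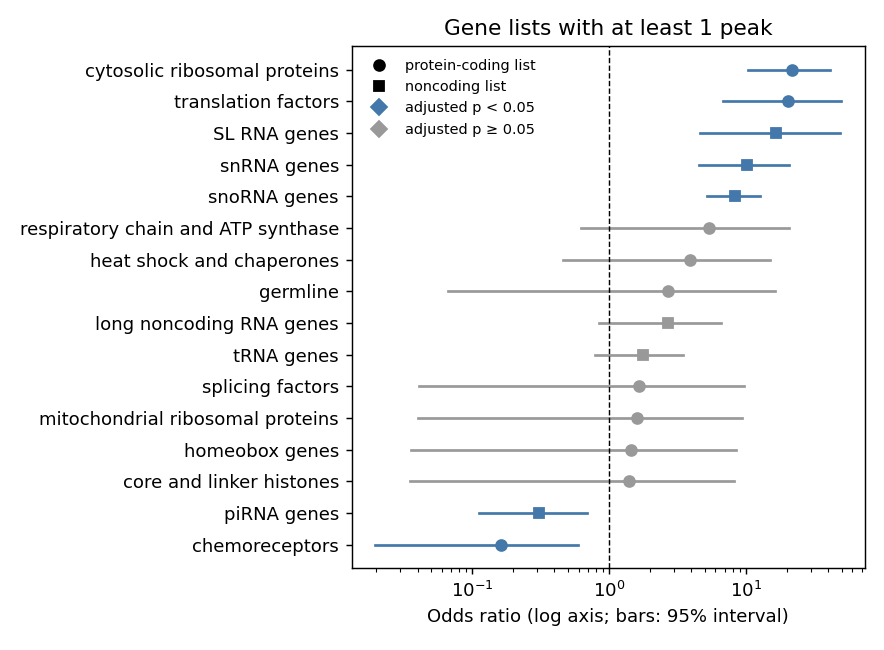
Odds ratio (horizontal log axis) with its 95% interval for each list with at least 1 peak (vertical axis); circles are protein-coding lists and squares noncoding lists, blue where the adjusted p is under 0.05. Cytosolic ribosomal proteins (21.6), translation factors (20.3), spliced leader RNA (16.6), snRNA (10.2) and snoRNA genes (8.31) lie above 1, and piRNA genes (0.311) and chemoreceptors (0.163) below.

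Which short sequences marked summits was tested with all 2080 6-base words, in windows reaching 50 bp to each side of the summit against windows of the same size 300 bp away on either side. Summit windows were richer in G and C (40.8% ± 10.1, SD, n = 368 windows) than flanking windows (36.5% ± 8.82, n = 736). Called were 19 words, all more frequent at summits, the only direction that the rule can call. The flanking windows were not matched for G and C content, so the test does not separate these words from the difference in base composition. The highest ratio was that of CGCGCG, in 9 of 368 summit windows against 1 of 736 flanking windows (ratio 18, adjusted exact p = 0.0475). CCCTGC was in 23 against 5 (ratio 9.20, adjusted exact p = 7.28e-05), CCTGCG in 21 against 5 (8.40, adjusted exact p = 0.000357) and ACGCAG in 37 against 11 (6.73, adjusted exact p = 5.57e-07). GCACGC and GCGCGC tied with 17 against 6 (5.67, adjusted exact p = 0.0143). CGCGCG did not pass with either replicate alone (ratio 6 without replicate 1 and 2.67 without replicate 2), with other windows (4 and 3.2), at the 184 highest peaks (2.67) or without X (14). GCACGC did not pass without replicate 1 (2.5) or replicate 2 (3), with other windows (3.5 and 2.88) or at the 184 highest peaks (8). ACGCAG did not pass without replicate 2 (2.63) or with windows reaching 25 bp (4), and its ratio was 4.83 without replicate 1. CCCTGC (3.6) and CCTGCG (4) did not pass without X. They passed in the other alternatives, with ratios of 5.43 for CCCTGC and 12 for CCTGCG without replicate 1, and 9.33 and 6.8 without replicate 2. The ratio of CCTGCG also rose to 26 with windows reaching 25 bp and 19 at the 184 highest peaks.

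The number of called words moved with the setting, from 2 without replicate 2 and 12 without replicate 1 to 195 against background regions. It was 7 with windows reaching 25 bp, 31 with windows reaching 100 bp and 6 at the 184 highest peaks.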

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

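The analyses without X, the miRNA biotype list and the correlations over all pooled regions, over the peaks of lower rank and without the 20 highest peaks were chosen after the data were seen; the other alternatives were planned. Of 168 values of the main results under alternatives, 133 kept their direction and side of the threshold or stayed within the set margin, 17 no longer passed, 3 newly passed, 14 moved and 1 turned direction past a threshold. The last was the Spearman correlation between replicates, -0.58 over the peaks of lower rank, and it no longer passed without the 20 highest peaks (0.034). For the lists that were not called and the 5 named words the numbers were 187, 15, 1, 0 and 0 of 203, and the 15 that no longer passed were all of named words. rRNA genes gave no value with a window of 250 bp, since no summit of either set lay near one. With the ce10 lists 378 peaks were optimal, and X passed as holding fewer peaks (0.749 times the expected number). Against background regions I (1.24), III (1.18) and V (0.763) no longer passed. Among the 184 highest peaks I (1.01), the intergenic class (0.667) and chemoreceptors (0.156) no longer passed, convergent (3.96) and divergent (0.275) neighbours newly passed, 68.5% of peaks were among the highest regions of both replicates, 1 list was lower and 6 words were called. With a window of 250 bp the intergenic class did not pass (0.949), with 1000 bp piRNA genes did not (0.501) and 1 list was lower, and against genes with a pooled region chemoreceptors did not (0.325) and 1 list was lower. Called words numbered 7 and 31 with windows reaching 25 and 100 bp, 195 against background regions and 8 without X. Leaving out each replicate in turn gave ranges of 57.6 to 69.0% for the share of optimal peaks among the 368 highest regions, where 1 replicate has to hold them in place of both, 1.14 to 1.37 for I, 0.651 to 0.781 for V, 0.935 to 0.983 for exons, 0 to 2 lists lower, 3.85 to 19.3 for translation factors, 0 to 0.219 for chemoreceptors, 0.365 to 0.695 for piRNA genes and 2 to 12 words. The 184 highest peaks give fewer counts by construction; for the other changes the cause was not tested. With all 261 genes of the miRNA biotype 3 summits were near a member (odds ratio 1.84, adjusted exact p = 0.52). Depth is unknown, and its effect was not tested. No paired analysis was possible because the replicates form 1 group.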

Other observations

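The tests of position, height, words, single replicates and gene density on X, and that of the motif on 3 outer bases, were chosen after their results or the heights by chromosome had been seen, as were those of repeated sequence by RNA class. The other tests of repeated sequence, that of all outer motif bases and those of neighbouring genes were set before their results were seen. The 50 peaks on X differed in position from the 318 on autosomes. Of the X summits 6 (12%) were at protein-coding 5′ ends against 139 (43.7%) on autosomes (Fisher's exact test, odds ratio 0.176, adjusted exact p = 2.12e-05), and 21 (42%) were intergenic against 28 (8.81%) (7.43, adjusted exact p = 1.41e-07). The shares at 3′ ends were 32 and 31.4% (adjusted exact p = 1). Against X background regions, X summits were more often at 3′ ends (32 against 17.4%, odds ratio 2.23, adjusted exact p = 0.0336) and less often in introns (6 against 28.1%, 0.164, adjusted exact p = 0.000875), while 5′ ends (12 against 14.2%, 0.821, 0.284 to 1.95, adjusted exact p = 1) and intergenic sequence (42 against 30.7%, 1.63, 0.879 to 2.98, adjusted exact p = 0.152) did not pass. Peaks on X were 1.18-fold higher in geometric mean (arithmetic means 75 ± 36.6 against 59.9 ± 19.5, SD, n = 50 and 318 peaks; adjusted permutation p = 0.0009). Among the 368 highest regions of replicates 1 and 2 alone the ratios were 1.13 in both (adjusted permutation p = 0.00213 each).

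Of the named words, CCCTGC and CCTGCG were more frequent at X than at autosomal summits. CCCTGC was in 14 of 50 summit windows on X and 9 of 318 on autosomes (Fisher's exact test, odds ratio 13.2, 4.92 to 37.2, adjusted exact p = 2.08e-07), and CCTGCG in 13 and 8 (13.4, 4.80 to 40.1, adjusted exact p = 2.7e-07). ACGCAG was in 5 of 50 windows on X and 32 of 318 on autosomes (10 and 10.1%, odds ratio 0.993, 0.287 to 2.76). CGCGCG (2 and 7 windows) and GCACGC (2 and 15) did not pass either.

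Of the 20 highest peaks 10 were on X, where 3.53 were expected by length (adjusted exact binomial p = 0.00145), and none of the 10 was at a protein-coding 5′ end. At least 8 of the 20 highest regions of each replicate lay on X, and 8% (3.15 to 18.8%) of X peaks held a repeated 36-base word. The lower gene density of X is already in its background regions. If X peaks kept to 5′ ends and out of intergenic sequence as autosomal peaks do, the odds ratios over background would be alike. Those of X peaks were 0.322 times the autosomal ones at 5′ ends (0.132 to 0.783), where only 6 X peaks lay. In intergenic sequence they were 3.60 times the autosomal ones (1.81 to 7.17, 95% Wald intervals). At 3′ ends the odds ratios over background were 2.23 on X and 2.08 on autosomes. The test was chosen with these values known, so it cannot decide whether gene density alone made the difference from autosomes. The intervals against X background given above do not exclude that X peaks fell at 5′ ends and in intergenic sequence as often as other X regions. A candidate explanation is that some of the X peaks are recruitment sites of the dosage compensation complex, which binds X in hermaphrodites and whose motif has the core GCGCAGGG; the core lay within 100 bp of 7 of the 10 X summits among the 20 highest (70.0%, 39.7 to 89.2%), 12 of all 50 X summits, 1 of 318 autosomal ones and 5 of 2844 X background summits (odds ratio for X peaks against X background 176, 54.6 to 671), but its reverse complement holds CCCTGC and CCTGCG, so these counts are not independent of the words that prompted them. Of the 4 motif bases outside the core (TC before, AG after), the 15 cores at X summits matched 2.73 ± 0.80 (SD) and the 298 elsewhere 1.13 ± 0.84 (permutation p = 2e-05, the smallest it can give). The 66 cores elsewhere on X, at none of these summits, matched 1.38 ± 0.96 (permutation p = 4e-05). All 4 bases matched at only 2 of the 15 cores at X summits and 1 of the 298 elsewhere. Without the base that the called word CGCGCA covers, the cores at X summits matched 1.93 ± 0.70 and those elsewhere 0.91 ± 0.72 of 3 (permutation p = 2e-05), though cores at the same summit are not independent. Open chromatin was not tested, the design has no contrast that would test dosage compensation, and 38 of all 50 X summits lacked the core.

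Of all peaks, 37 (10.1%) lay at snoRNA, snRNA or spliced leader RNA genes. Reads from near-identical gene copies could raise such peaks, and 29.7% (17.5 to 45.8%) of them held a repeated word, against 4.09% of background regions. For the 27 at snoRNA genes the share was 14.8% (5.92 to 32.5%), above the 4.09% of background regions. Most of these 27 thus held no exactly repeated word at the points tested. Copies that differ within a word, and repeats between the points, are not counted. The test therefore cannot decide whether near-identical copies raised the peaks at snoRNA genes. For the 10 at snRNA and spliced leader genes the share was 70.0% (39.7 to 89.2%). This interval spans 50%, so for these 10 repeats cannot be told apart from binding. Neighbouring protein-coding promoters were argued against, since without summits within 500 bp of a protein-coding 5′ end the odds ratio was 14.5 (9.26 to 22.1). High transcription of these genes stays open and untested, as does any biological explanation.

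The peaks at ribosomal protein and translation factor genes could come from small RNA genes near them. Without summits within 500 bp of a snoRNA, snRNA, spliced leader or tRNA gene all 18 member genes still had a peak, and the odds ratio was 23.3 (12.9 to 39.9). None of the 18 peaks held a repeated word (0%, upper bound 17.6%). Signal that follows high transcription or open chromatin whatever the tagged protein stays open, since neither a control nor another factor was analysed here, and no biological explanation was tested.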
